A study of Acinetobacter baumannii with 4 samples.

How the data were processed

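The samples were 4 two-colour custom Agilent arrays of *Acinetobacter baumannii* ATCC 17978. Arrays 1, 2 and 3 held biological replicates 1, 2 and 3 with treated RNA in Cy5 and untreated RNA in Cy3, and array 4 held replicate 1 with the dyes exchanged, per the labels. Cultures kept at 37 °C and shaken at 200 rpm were divided into 15 mL parts at an OD600 of 0.75. After 30 min the OD600 was 1.35 in the untreated and 1.25 in the treated part, per the labels' protocols.

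The authors deposited 1 scanner file per array and 1 table of the series. The scanner files hold spot intensity values in both channels, made with Agilent Feature Extraction 10.5.1.1 per the file headers. They also hold a log10 ratio of red over green that this software computed from its processed signals, and flags for spots that are well above background, saturated or outliers, per the file headers. The authors' deposited table holds a log2 ratio per locus tag and array. Its columns followed the mean of the scanner software's log10 ratios per gene, put on log2, at r = 1.000, 0.999, 1.000 and 0.999 for arrays 1 to 4, with the sign of array 4 turned. They thus run as treated over untreated by the dyes in the labels, while the table's header names control over treated. Their medians lay between -0.04 and -0.01, and the software's normalization settings were not examined here.

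All arrays lay on 1 slide per the file headers, so no slide effect was tested. In the file of array 4 the columns of probe names and gene identifiers are exchanged, so both were taken from array 1 by spot number. Of 15744 spots, 536 were controls, and 132 probes printed at 10 spots each were repeats of single probes and were left out of the comparison. Over these repeats the ratios correlated with those of the single probes at r between 0.921 and 0.961. No gene spot carried the saturation flag.

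Signals were corrected with limma 3.58.1 in R 4.3.3 by normexp with an offset of 50. Median spot signals and median local backgrounds were used, since mean signals, which the design had assumed, were not among the columns used here. Ratios were normalised within each array by loess with control spots and outlier spots at weight 0. Spots flagged as outliers, between 285 and 490 gene spots per array, were left out, and spots of 1 probe were averaged. A probe was kept if it was well above background in at least 1 channel in at least 2 of the 3 replicates, which removed 2 of 13468 probes. A gene was the mean of its kept probes. The sign of array 4 was turned, and arrays 1 and 4 were averaged as replicate 1. The treated and untreated parts of a culture shared an array, so the pairing is within each ratio. One gene lacked a value on 1 array.

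The mean log2 ratio over 3 replicates was tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over 3367 genes and a threshold of 0.05; the total degrees of freedom were 7.60. Intervals of folds are 95% intervals of this fit. Levels per channel are normalised log2 intensities after loess and quantile normalization of mean intensities between arrays, and they are open to dye bias in replicates 2 and 3.

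Gene lists were fixed before the data were examined by locus tag or product. The files used here and the reference table, which covers another strain and matched 0 of the locus tags, do not pair the tags with products. Of 24 fixed lists, 9 had locus tags and could be used, and 15 defined by product were not analysed. A further 6 lists of locus tags were added after the files were opened and before the ratios of their genes were looked at. The tags of the fixed and the added lists were set from recall of the published annotation and were not checked against a table, so list membership is uncertain. Gene names are those of the strain's published annotation, given as background. Lists of at least 4 measured genes, 11 in all, were tested with limma's fry for a shift in one direction and with camera at a preset correlation of 0.01 and at an estimated one, each adjusted over the lists. At an estimated correlation camera uses the 2 residual degrees of freedom of the fit, which leaves it little power. Named genes were all genes of the preset efflux and envelope list; up to 12 genes with the largest increase and 12 with the largest decrease among those past the threshold with the same sign on all arrays; and up to 4 called members of each list, or the 2 with the smallest p where none was called. The *groEL* gene and A1S_1338 to A1S_1343 were added after their values were seen.

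The procedure was tested on simulated data. Spots of 200 genes were given known log2 changes on the real intensities and replicate spread of the 3367 genes. The test called 64% of the genes raised by 1 log2 unit, 68% of those lowered by 1, and 98% each of those raised or lowered by 2. It called 4 of 3147 unchanged genes. A list of 20 genes shifted by 0.5 had a recovered median of 0.48. The 200 changed genes ease the Benjamini-Hochberg cutoff compared with the real data, where 22 genes were called. Noise was drawn independently for each gene, while camera's estimated correlation within real lists reached 0.93. The shares called and the list result therefore need not hold for the real arrays.

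Alternatives were the scanner software's ratio, no background subtraction, median centring in place of loess, scaling between arrays, no or a strict filter on dim probes, the median or brightest probe per gene, a dye term over 4 arrays, the swapped array left out, each replicate left out, and eBayes with a trend or robust. In the fit with a dye term array 4, the only one with the dyes exchanged, weighs as much as the other arrays together. Replicate 1 thus has the most weight in that fit. Median centring shifts each array by a constant and leaves in any dye trend with intensity. A ratio of a bright or dim gene that moves under it may therefore reflect such a trend. Stricter thresholds, camera's correlation and the authors' deposited log2 values were also set beside the results.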

Results

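*Acinetobacter baumannii* ATCC 17978, a Gram-negative laboratory strain of an opportunistic pathogen, was grown in liquid culture and shocked with chlorhexidine, a biguanide disinfectant that acts on bacterial membranes. Each of 3 biological replicates was a culture divided into a treated part, given 4 µg/mL chlorhexidine (0.5 of the minimum inhibitory concentration) for 30 min, and an untreated part. RNA of both parts was labelled with different dyes and hybridised together on one 2-colour oligonucleotide array. Replicate 1 was hybridised again with the dyes exchanged, which made 4 arrays in all, and both arrays of replicate 1 were averaged so that n was 3. The arrays measured 3367 genes, of which 3362 carried a locus tag, mostly with 4 probes per gene. The median signal of the gene spots lay between 892 and 2937 in the red channel and between 1161.5 and 3370 in the green channel, against median local backgrounds of at most 49.5 and 24. Between 99.7% and 100% of the gene spots were well above background in each channel of each array. The number of arrays limits the precision.

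The question was which genes changed their transcript level after a short chlorhexidine shock. All log2 ratios are treated over untreated, a direction taken from the dyes in the labels; the header of the authors' deposited table names the opposite ratio, although its values run in the direction used here. The largest increases were those of 2 drug efflux systems. The AdeAB block, which encodes a multidrug efflux pump of the RND family, rose 25.4-fold for A1S_1750 (95% confidence interval 19.0 to 33.8), 24.4-fold for A1S_1751 (16.4 to 36.3) and 14.5-fold for A1S_1752 (11.3 to 18.6). The gene *aceI* (A1S_2063), which encodes a chlorhexidine efflux protein of the PACE family, rose 10.9-fold (6.06 to 19.5). By the strain's published annotation, the 3 called genes with the largest decreases each encode a chaperone or co-chaperone. This grouping was made after their values were seen and was not tested. The co-chaperonin gene *groES* (A1S_2665) was 4.85-fold lower (3.17 to 7.41), *dnaK* (A1S_2960) 3.92-fold lower (2.38 to 6.45) and *grpE* (A1S_2959) 3.12-fold lower (2.06 to 4.74).

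In limma's moderated test with Benjamini-Hochberg adjustment over all genes, 11 genes were higher and 11 lower at an adjusted p under 0.05, and 6 of the former and 9 of the latter changed at least 2-fold. All 22 had the same sign on all 4 arrays, which their selection by a test on these arrays makes likely in advance. At an unadjusted p under 0.05 there were 650 genes, 291 higher and 359 lower. The count was sensitive to the processing: with the scanner software's own ratios 3 genes were higher and 0 lower, with median centring in place of loess 4 and 0, and with a variance trend on intensity 67 and 79. The calls also depended on single replicates, with 11 higher and 6 lower without replicate 1, 7 and 11 without replicate 2, and 52 and 88 without replicate 3. The 22 genes kept their sign in each of 16 alternative fits, but these used the arrays on which the genes were selected.

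**Figure D1:**
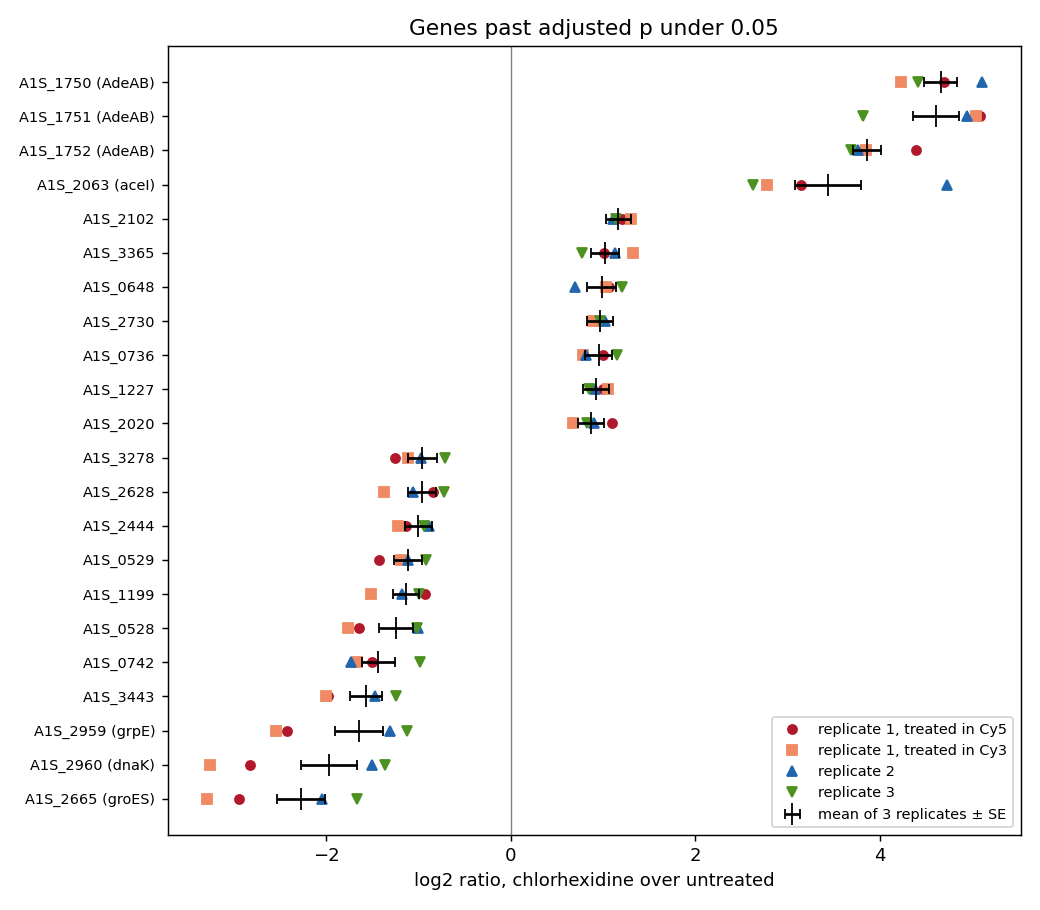
The log2 ratio of chlorhexidine over untreated (x axis) is drawn for each of the 22 genes past an adjusted p of 0.05 (y axis), with 1 symbol per array and a bar for the mean of 3 replicates ± SE. The AdeAB tags and *aceI* stand between 3.44 and 4.66, while every other gene has a mean between -2.28 and 1.17.

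The increase of *aceI* was 3.44 on the log2 scale (SE 0.36, adjusted p = 0.0146), with 2.97 in replicate 1, 4.73 in replicate 2 and 2.63 in replicate 3. Its normalised log2 intensity was 8.30 ± 0.67 (SD, n = 3) in untreated and 11.74 ± 0.81 in treated cells. Its 4 probes gave means between 3.19 and 3.77. The size of the increase was similar with the scanner software's ratios at 3.86 and with the brightest probe alone at 3.52, but the adjusted p was then 0.0657 and 0.0856. Without replicate 2, which gave the highest ratio, it was 2.80 with an adjusted p of 0.000134. Over its 16 alternative fits the adjusted p of A1S_2063 ranged from 0.000134 to 0.0856. The neighbouring *aceR* (A1S_2064), which encodes the regulator of *aceI*, stood at 0.21 (adjusted p = 0.442), and at -0.13 with median centring.

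The AdeAB tags had log2 ratios of 4.66 (SE 0.18, adjusted p = 2.29e-05) for A1S_1750, 4.61 (SE 0.25, adjusted p = 0.00014) for A1S_1751 and 3.86 (SE 0.15, adjusted p = 2.29e-05) for A1S_1752. These 3 genes passed the threshold in all 16 alternative fits, and no other gene did. They were also the only ones past an adjusted p of 0.01. The probes of A1S_1752 disagreed in size, with means from 3.14 to 4.92, and this was the only one of the 22 genes whose probes spanned over 1 log2 unit. With the brightest probe alone A1S_1750 was at 3.97 and A1S_1752 at 3.14. The 3 genes were at 5.11, 4.94 and 4.12 with the scanner software's ratios, and at 5.06, 4.94 and 4.32 in the authors' deposited table. The size of the increase thus depended on the processing, which the intervals of the folds do not include. The genes on either side did not pass the test. A1S_1753 and A1S_1754, which encode the AdeRS two-component regulator of the pump, stood at 0.53 (adjusted p = 0.177) and 0.28 (adjusted p = 0.34; -0.011 with median centring). A1S_1749 was at -0.14 with replicate values of -0.60, -0.69 and 0.86, and A1S_1755 was at 0.22 (-0.22 with median centring).

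Among the 12 efflux pump genes listed before the data were examined, 4 rose, 0 fell and 8 did not pass the threshold; adjusted over the list alone, 5 rose and 0 fell. The fifth was *craA*. This list, and the preset list that contains it, held *aceI*, which was known beforehand from the literature to respond to chlorhexidine. Its rise within them is therefore not independent support for a shift of efflux genes. The AdeIJK genes A1S_2735, A1S_2736 and A1S_2737 were at 0.18, 0.11 and -0.14, and the AdeFGH genes A1S_2304, A1S_2305 and A1S_2306 at -0.37, -0.60 and 0.00, with opposite signs in replicates 2 and 3 for each of the latter. The regulator gene A1S_2303 beside them was at 0.22. The transporter genes *amvA* (A1S_2057) and *craA* (A1S_3146), both for major facilitator pumps, were at 0.37 (adjusted p = 0.211) and 0.69 (adjusted p = 0.148). Without replicate 3 *craA* (A1S_3146) was at 0.99 and passed the threshold with an adjusted p of 0.0271. The outer membrane protein genes *ompA* (A1S_2840) and *carO* (A1S_2538) had ratios of -0.09 and -0.33, and their arrays of replicate 1 differed by dye, with -0.16 against -1.77 and -0.25 against -1.76. A dye term over 4 arrays gave -0.80 for A1S_2840 (adjusted p = 0.102) and -0.91 for A1S_2538, which passed with an adjusted p of 0.0450. That fit gives replicate 1 the most weight. With median centring A1S_2840 and A1S_2538 were at 0.85 and 0.58, and without replicate 1 at 0.35 and 0.013.

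In limma's fry test of a shift in one direction, the efflux pump list had a median log2 ratio of 0.27 and an adjusted p of 0.0224, against an adjusted p of 0.245 in camera with an estimated correlation. The list of 20 preset efflux and envelope genes, which holds all 12 of them, had 4 higher and 0 lower genes (5 and 0 adjusted over the list alone), a median of 0.21 and the same adjusted p in both tests. At its preset correlation camera gave an adjusted p of 8.42e-06 for the efflux pumps and 1.19e-05 for the preset genes. The estimated correlations were 0.036 and -0.052. With 2 residual degrees of freedom, camera at an estimated correlation cannot tell a missing shift from low power. Neither list passed fry once the genes called on their own were left out, with medians of 0.06 and 0.14 and an adjusted p of 0.55 for both. Scaling between arrays ended both calls, with an adjusted p of 0.125 for the efflux pumps and 0.0996 for the preset genes. Leaving out any 1 replicate also did so, with an adjusted p between 0.178 and 0.316 and between 0.141 and 0.216. Such fits leave fry fewer residual degrees of freedom, and no list passed in any of them. They cannot tell a fragile shift from low power, and the medians stayed between 0.25 and 0.33 and between 0.18 and 0.26. The medians of the efflux pump and preset lists were 0.62 and 0.50 with median centring and 0.18 and 0.11 with the brightest probe, and both calls were kept there.

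The 4 chaperone genes given here were grouped after their values were seen. The fixed list of chaperones and quality-control proteases was not analysed, since no table paired the locus tags with products. Other chaperone genes were not identified, so the values do not show a fall of chaperone genes as a class. The log2 ratios were -2.28 (SE 0.26, adjusted p = 0.0187) for *groES* (A1S_2665), -1.97 (SE 0.31, adjusted p = 0.0472) for *dnaK* (A1S_2960) and -1.64 (SE 0.26, adjusted p = 0.0472) for *grpE* (A1S_2959). The chaperonin gene *groEL* (A1S_2664), the neighbour of *groES*, had a ratio of -2.18 and an adjusted p of 0.0509, just outside the threshold. *groEL* (A1S_2664) passed without replicate 1, 2 or 3, with ratios of -1.53, -2.39 and -2.60 and an adjusted p of 0.0123, 0.0398 and 0.0271. It also passed with scaling between arrays (adjusted p = 0.0293), the median of the probes (0.0484), a dye term (-2.90, adjusted p = 0.0122) and a variance trend (0.0128). With median centring A1S_2664 was at -1.37 (adjusted p = 0.309). All 4 genes were lower on every array, which their choice by values on these arrays makes likely in advance. Replicate 1 gave the lowest ratio for each, for example -3.12 for *groES* against -2.04 and -1.67 in replicates 2 and 3. In treated cells *dnaK* had a normalised log2 intensity of 14.19 ± 1.04 (SD, n = 3), against 16.16 ± 0.13 in untreated cells. None of the 3 called genes passed with the scanner software's ratios, the brightest probe or median centring, where *groES* had ratios of -2.38, -2.30 and -1.65, *dnaK* -2.08, -2.01 and -1.32, and *grpE* -1.64, -1.75 and -1.33. The calls of *dnaK* and *grpE* were also lost without background subtraction (adjusted p = 0.0509 for both) and with robust eBayes (adjusted p = 0.0507 for both), and that of *grpE* without the swapped array (adjusted p = 0.0501), at ratios between -1.97 and -1.62.

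The other 15 called genes have no product in the files. The 7 that rose lay between 0.87 and 1.17, led by A1S_2102 at 1.17 (SE 0.14, adjusted p = 0.0201), followed by A1S_3365 at 1.02 and A1S_0648 at 0.99; A1S_2730, A1S_0736, A1S_1227 and A1S_2020 completed them. The 8 that fell lay between -1.57 and -0.96. They were led by A1S_3443 at -1.57 (SE 0.18, adjusted p = 0.0187) and A1S_0742 at -1.44 (SE 0.18, adjusted p = 0.0223). The adjacent A1S_0528 and A1S_0529 fell by 1.24 and 1.11 on the log2 scale. A1S_1199, A1S_2444, A1S_2628 and A1S_3278 made up the rest. With median centring A1S_1199 was at -0.39 (adjusted p = 0.433) and A1S_2628 at -0.23 (adjusted p = 0.668).

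The phenylacetate catabolism genes A1S_1335 to A1S_1349, which encode the breakdown of phenylacetate, had positive mean ratios for all 15 members, with a median of 0.59, but none passed the threshold over all genes. Adjusted over the list alone 10 rose and 0 fell. The replicates were unlike one another. The list's median was 0.20 in replicate 1, 1.05 in replicate 2 and 0.94 in replicate 3. For A1S_1336 the ratios were 0.43, 2.95 and 2.51, with a mean of 1.96 (adjusted p = 0.0887), and for A1S_1337 they were 0.39, 2.56 and 2.42. Without replicate 1 the ratio of A1S_1336 was 2.73 and passed with an adjusted p of 8.05e-05. With a variance trend A1S_1336, A1S_1337 and A1S_1338 passed with an adjusted p of 0.0280, 0.0301 and 0.0406. With a dye term over 4 arrays A1S_1336, A1S_1337 and A1S_1338 were at 1.22, 1.03 and 0.96, with an adjusted p of 0.184, 0.177 and 0.264. That fit gives replicate 1, where the ratios were lowest, the most weight. The fry test gave an adjusted p of 0.239 for the list, and camera an adjusted p of 7.45e-08 with its preset correlation and of 0.341 with an estimated correlation.

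**Figure D2:**
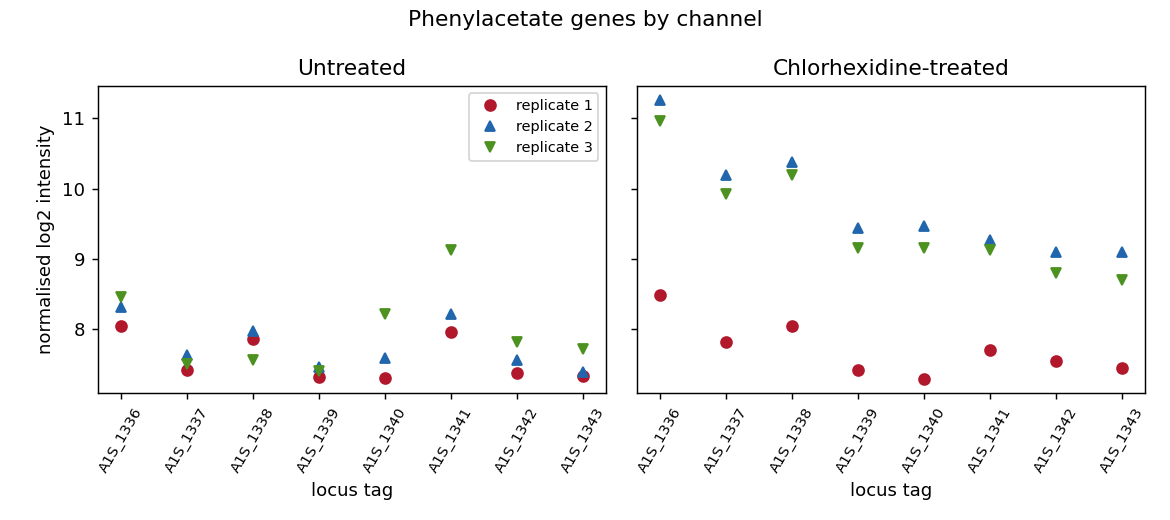
The normalised log2 intensity (y axis) of A1S_1336 to A1S_1343 (x axis) is drawn per replicate for untreated cells on the left and chlorhexidine-treated cells on the right. For A1S_1336 the untreated levels were 8.05, 8.31 and 8.46 in replicates 1, 2 and 3, and the treated levels were 8.48, 11.27 and 10.97.

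The 18 genes of the capsule locus A1S_0049 to A1S_0066, a list set from recall of the published annotation after the files were opened but before the ratios of its genes were looked at, had a median of -0.26 and a fry adjusted p of 0.0224, against an adjusted p of 0.245 in camera with an estimated correlation. Camera at its preset correlation gave the capsule list an adjusted p of 0.00151. At the estimated correlation of -0.032 camera had 2 residual degrees of freedom and thus little power. Of the members of the capsule list 17 had a negative mean, but none passed on its own, also adjusted over the list alone. The lowest p belonged to A1S_0065 at -0.58 and A1S_0058 at -0.58, and A1S_0058 passed with a variance trend (adjusted p = 0.0486). Median centring in place of loess ended the call, with a median of 0.045 and an adjusted p of 0.937. Scaling between arrays ended the call with an adjusted p of 0.0996. Leaving out any 1 replicate also did so, with an adjusted p between 0.13 and 0.241, but no list passed in those fits, which have fewer residual degrees of freedom. The capsule median stayed between -0.27 and -0.24 in them.

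No gene of the remaining lists passed over all genes and no such list passed the fry test. The 20 type VI secretion genes had a median of 0.22 with 19 positive members (adjusted p = 0.559), and of -0.020 with median centring. Their replicate medians were 0.40, -0.15 and 0.57, and A1S_1299 and A1S_1298 were at 0.58 and 0.47. The 13 genes of respiratory complex I all had negative means and a median of -0.29 (adjusted p = 0.559; 0.17 with median centring), with -0.74 in replicate 2 against -0.09 and -0.01 in replicates 1 and 3. Its tags A1S_0762 and A1S_0763 were at -0.62 and -0.59, and at 0.045 and 0.077 with median centring. With replicate medians of 0.08, -0.51 and 0.02, the 8 ATP synthase genes had a median of -0.12 (adjusted p = 0.559), and of 0.55 with median centring. Of these A1S_0157 at -0.77 (adjusted p = 0.0942) passed when adjusted over the list alone and with a variance trend (adjusted p = 0.0475), but was at -0.12 with median centring (adjusted p = 0.776), and A1S_0155 was at -0.24. The 21 acinetobactin genes, for the strain's siderophore, had a median of 0.02 (adjusted p = 0.966), with A1S_2387 and A1S_2385 both at 0.36. The 6 Csu pilus genes had a median of 0.00 (adjusted p = 0.994), with A1S_2217 at 0.15, not well above background in all probes, and A1S_2218 at -0.12. The 11 genes of the acinetin and quorum sensing locus had a median of -0.03 (adjusted p = 0.994), with A1S_0109 at -0.52 and A1S_0111 at 0.29.

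The 4 genes of the BfmRS and BaeSR two-component systems had a median of -0.29 (adjusted p = 0.182), and 2 of them were lower when adjusted over the list alone. The envelope response regulator gene *bfmR* (A1S_0748) was at -0.91 with an adjusted p of 0.0624, and its replicate values were -1.08, -1.06 and -0.59. A1S_0748 passed with scaling between arrays (adjusted p = 0.0488), a dye term (0.0374), a variance trend (0.0210) and without replicate 3 (-1.07, adjusted p = 0.0271), but it was at -0.33 with median centring (adjusted p = 0.556). Lists of fewer than 4 genes were not tested as sets. Of the DNA damage genes, *recA* (A1S_1962) was at -0.56 (adjusted p = 0.119; lower when adjusted over the list alone) and *umuDAb* (A1S_1389) at 0.07. The 3 *pga* genes for the biofilm polysaccharide PNAG lay between 0.27 and 0.38, with A1S_2162 at 0.38 and A1S_2161 at 0.37. The 3 genes of *pmrCAB*, a lipid A modification system, lay between -0.35 and -0.05, with A1S_2751 at -0.35 and A1S_2750 at -0.11.

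Both arrays of replicate 1, with opposite dyes, correlated at r = 0.886 across genes after the sign was turned, where genes are not independent replicates. Arrays of different replicates correlated less, at 0.616 for arrays 1 and 2, 0.503 for arrays 1 and 3 and 0.319 for arrays 2 and 3. The swapped array 4 correlated at 0.518 with array 2 and 0.362 with array 3. The median absolute dye effect, the difference between the arrays of replicate 1 divided by 2, was 0.06 log2 units, and 566 genes differed in sign between them, none of which was among the 22. The gene means correlated at r = 0.992 and rho = 0.992 with the mean of the authors' deposited table over 3362 genes, in which *aceI* (A1S_2063) had a mean of 3.86 and A1S_1750 one of 5.06.

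**Figure D3:**
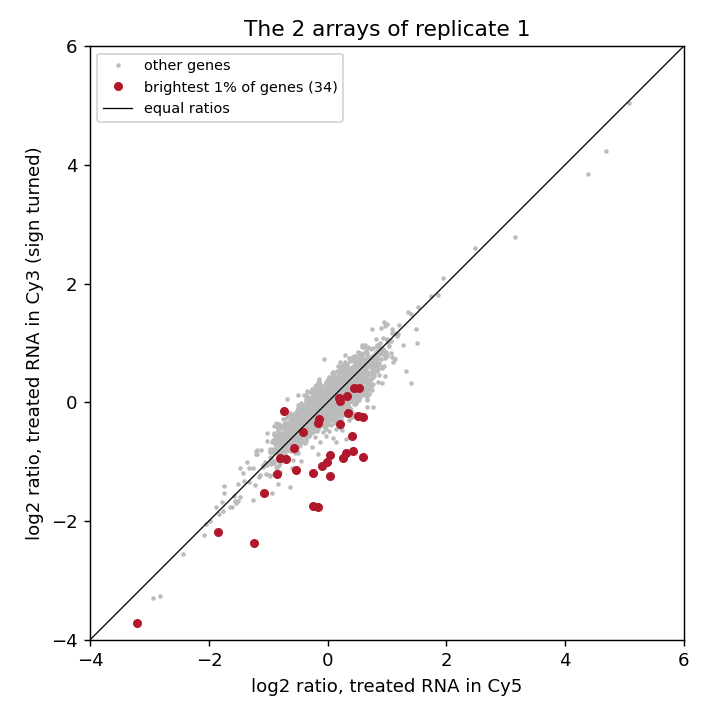
The log2 ratio of each gene on the array with treated RNA in Cy5 (x axis) is drawn against that on the array with treated RNA in Cy3, sign turned (y axis), for replicate 1. Grey points are genes, red points are the 34 brightest genes, and 33 of the latter lie below the line of equal ratios.

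Genes with adjacent locus tag numbers had similar ratios. The median absolute difference over 3302 adjacent pairs was 0.19 log2 units, against a median of 0.29 in 10000 random orders of the genes, and no random order was as low (permutation p = 1e-04, one-sided, the smallest these orders can give). At a tag distance of 2 the median difference was 0.24 (permutation p = 1e-04).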

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

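A signal appeared on repeated spots left out of the comparison, and it was that of the single spots they repeat. A1S_2730, the only gene past the threshold among the 33 genes with such spots, had a log2 ratio of 0.99 ± 0.05 (SD, n = 3) on them, against 0.97 on its single spots, and it was above its untreated level on all 4 arrays.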

How the results depend on the processing

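The subtraction of the median of all genes and the removal of called genes from the lists were chosen after the data were seen. The 22 called genes kept their sign in all 16 alternative fits, and 3 of them, the AdeAB tags, passed in each. Of the 22, 9 passed in all 3 fits that left out a replicate. The other counts of genes higher and lower were 3 and 0 with the scanner software's ratio, 8 and 7 without background subtraction, 4 and 0 with median centring, and 21 and 21 with scaling between arrays. They were 3 and 0 with the brightest probe, 26 and 45 with a dye term over 4 arrays, 67 and 79 with eBayes with a trend, and 8 and 7 with robust eBayes. At an adjusted p under 0.01 they were 3 and 0, and 6 and 9 at a change of at least 2-fold. The causes were not tested. Without 1 replicate, between 7 and 52 genes were higher and between 6 and 88 lower. The dye term counts both arrays of replicate 1 as separate, so it has 1 more sample, and array 4 weighs as much as the other arrays together. It gives replicate 1 the most weight and cannot separate a dye effect from a difference between replicates. The log2 ratio of *aceI* was 3.86 with the scanner software's ratio and 3.52 with the brightest probe, both outside the threshold, and 2.80 without replicate 2. A dye term gave -2.58 for *dnaK* (A1S_2960). A fit with replicate as a random block could not be run, since 4 arrays in 3 blocks gave a block correlation for 0 genes.

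The number of lists past the threshold was 3 in the main setting, 2 with median centring, 0 with scaling between arrays, 0 with any replicate left out, 0 with camera at an estimated correlation, 7 with camera at its preset correlation, and 1 with called genes left out of the lists. That 1 list was the capsule locus, which held no called gene and kept its 18 members (fry adjusted p = 0.0498). The efflux pump and preset lists, which lost members, did not pass (fry adjusted p = 0.55 for both). With a replicate left out fry has fewer residual degrees of freedom, so the count of 0 there cannot tell fragile shifts from low power. The count of 0 with camera at an estimated correlation has a like limit, since that test has 2 residual degrees of freedom. Correlation with the authors' deposited table was 0.999 with the scanner software's ratio.

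No called gene turned its sign. With median centring, the ratio was -0.13 for A1S_2064, -0.011 for A1S_1754, -0.22 for A1S_1755, 0.50 for A1S_2737, -0.31 for A1S_2306, 0.85 for A1S_2840, 0.58 for A1S_2538, 0.52 for A1S_0155, -0.21 for A1S_2217, 0.036 for A1S_0065, 0.077 for A1S_0763, 0.045 for A1S_0762 and -0.078 for A1S_1341. Of these, the genes that turned positive had mean log2 intensities between 15.25 and 16.69, and those that turned negative between 6.59 and 8.69. Median centring leaves in a dye trend with intensity, and treated RNA was in Cy5 on arrays 1, 2 and 3. These turns therefore cannot tell an uncorrected dye trend from an unstable treatment ratio. List medians with median centring were 0.55 for ATP synthase, -0.29 for acinetobactin, -0.020 for type VI secretion, 0.045 for the capsule locus and 0.17 for complex I. Other sign changes were -0.00039 for A1S_2306 without background subtraction, 0.18 for A1S_2840 without the swapped array, -0.026 for A1S_1389 with the brightest probe and -0.098 with the dye term. List medians turned to 0.030 for ATP synthase and 0.11 for Csu with the dye term, -0.016 for acinetobactin with the brightest probe, 0.022 for Csu without the swapped array and 0.022 with the median of all genes subtracted, and 0.019 for the acinetin locus with scaling between arrays.

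Leaving out each replicate gave -0.65 to 0.13 for A1S_1749, -0.045 to 0.26 for A1S_2736, -0.78 to 0.024 for A1S_2304, -0.086 to 0.11 for A1S_2306, -0.53 to 0.35 for A1S_2840, -0.62 to 0.013 for A1S_2538, -0.046 to 0.22 for A1S_1389, -0.28 to 0.064 for A1S_2218 and -0.12 to 0.53 for A1S_1341. List medians ranged from -0.28 to 0.082 for ATP synthase, -0.17 to 0.12 for acinetobactin, -0.13 to 0.13 for Csu and -0.36 to 0.12 for the acinetin locus. Signal over background limited few genes, since 2 of 13468 probes fell to the filter.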

Other observations

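The scan of the chromosome and the tests of the phenylacetate genes and of the brightest genes were chosen after the results were seen; the sign assignments and the comparison of adjacent genes were planned. In windows of 10 consecutive measured tags, the highest mean ratios were 1.46 at A1S_1747 to A1S_1756 around AdeAB (permutation p = 1e-04 over 10000 random orders, the smallest they can give), 1.07 at A1S_1335 to A1S_1344 (permutation p = 3e-04) and 0.78 at A1S_0643 to A1S_0652 (permutation p = 0.028). The stretch A1S_0633 to A1S_0655 had positive means for 22 of 23 genes, of which 1, A1S_0648, passed the threshold. In the window A1S_0643 to A1S_0652 the mean was 1.36 in replicate 1, 0.20 in replicate 2 and 0.79 in replicate 3. The lowest windows were A1S_2949 to A1S_2960, which ends in *grpE* and *dnaK*, at -0.55 (permutation p = 0.035), A1S_3123 to A1S_3132 at -0.53 (permutation p = 0.046) and A1S_0524 to A1S_0533 at -0.53 (permutation p = 0.06). These p-values are one-sided and compare each window with the most extreme window of each random order, over genes that are not independent replicates. The windows that start at A1S_1747, A1S_0643, A1S_2949 and A1S_0524 hold called genes, so their p-values are not separate from those calls. Random orders also break up the likeness of adjacent genes, which the window p-values therefore include.

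The genes A1S_1336 to A1S_1343 had higher ratios in replicates 2 and 3 than in replicate 1. A dye bias shared by the arrays would cancel in the mean of replicate 1 and stay in the others. It is argued against, since the dye effect of these genes in replicate 1 had a median of 0.027 log2 units (SD 0.077 over the genes), while the gap between the replicates had a median of 1.59. Single aberrant probes are argued against, since 100% of the 32 probes read higher on both arrays 2 and 3 than on array 1. A higher starting level in the untreated part of replicate 1 would lower its ratio, but that level was -0.27 log2 units (SD 0.26) relative to the other replicates, while the treated level differed by -1.95 (SD 0.45). A difference between the cultures in their response, timing or handling may remain as a hypothesis, and it was not tested because the labels give nothing but the replicate number.

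The brightest 1% of genes, 34 in number, read higher with treated RNA in Cy5 than in Cy3 in replicate 1, with a positive dye effect for 33 of them and a median of 0.27 log2 units against -0.01 for the other genes. That the loess fit created the excess over other genes is argued against, since it was 0.28 after loess and 0.56 after median centring. The scanner software's ratio gave 0.30, but its normalization was not examined. Too little correction by loess at the bright end would leave such an excess, and these values cannot exclude it. Saturated spots are argued against by the flags, with 0 of 624 spots of these genes saturated. A channel response that is not linear below saturation may account for it and was not tested. The same 2 extracts were on both arrays, so no biological explanation applies, and none of the 22 called genes was among the 34, although *ompA* and *carO* were bright genes of this kind.

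Treated and untreated can be assigned to the 3 replicates in 4 ways, counting a mirror once. The real assignment gave 22 genes and the highest of the others 0, so 1 of 4 gave as many. These are too few for a share under 0.05.

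The hypothesis that neighbouring genes share transcripts predicts that adjacent genes have ratios closer together than random pairs. The median absolute difference of 0.19 between adjacent genes, against a minimum of 0.27 over 10000 random orders, is consistent with it, but a bias that follows position on the chromosome could give the same and was not tested.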
